A study of Mus musculus with 10 samples.

How the data were processed

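Liver DNA of 10 mice was hybridised to 2-colour Agilent oligonucleotide arrays for comparative genomic hybridisation, 1 animal per array, with the animal's DNA in Cy5 and the pooled reference in Cy3 per the labels. DNA was isolated after proteinase K digestion with a column kit, per the labels' protocols. Groups, sexes and replicate numbers were taken from the labels. The replicates are separate animals. The arrays sat on 3 slides, of 4, 4 and 2 arrays, each holding both groups equally, and were all scanned on 1 day.

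The deposited scanner files hold spot intensities. The processed intensity of each channel was background-subtracted and dye-normalised with a linear factor by Feature Extraction 10.7.3.1 under its CGH protocol, per the file headers, and the median spot and background intensities are uncorrected, per the file headers. The deposited value table holds log10 ratios that were identical to the log10 ratio column of the scanner files, so their direction is Cy5 over Cy3, with column medians from -0.0035 to 0.0033 and no further centring. Differences from the processed intensities were seen at 1 to 3 probes per array, at a tolerance of 0.001. The submitters' processing notes name Partek 6.5 without a role. Coordinates are those of the files. The headers of 6 arrays name mm9, and the other 4, which name no build, carry the same probe coordinates.

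Control spots were left out and the replicate spots of a probe were averaged, which left 170305 probes, 161460 of them on autosomes, 8723 on chromosome X and 122 on chromosome Y. The log2 ratio of processed intensities was centred on each array's median over autosomal probes, with no loess or quantile step, since a copy number change may shift many probes one way. Spots with an outlier flag, from 122 to 195 per array, stayed in and were left out in an alternative. Signal over noise per the file headers was between 57.9 and 72.8 in Cy3 and between 49.6 and 62.2 in Cy5. The spread of differences between neighbouring probes, per the file headers, was between 0.14 and 0.15 on 7 arrays. It was 0.20 and 0.21 for ICSI-derived replicates 1 and 4 and 0.17 for naturally born replicate 2. Segments are harder to find on such arrays.

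Probes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group and sex in the model, two-sided, Benjamini-Hochberg adjustment at 0.05), separately for autosomes and chromosome X. Called probes of one direction less than 200 kb apart were merged into loci of at least 3 called probes. Each autosomal profile was split into constant means by optimal partitioning with a penalty factor of 3 and at least 5 probes, after single probes beyond 4 robust SD of their 10 neighbours had been drawn in. A segment was called at an absolute mean of 0.25 or more. Overlapping segments of all animals were merged into regions, and the core of a region is the longest run of probes covered in the most animals. Values per animal were compared by exact permutation tests. The groups, the tests of the comparisons, the rule for named items and the alternatives were set before the data were examined, except the alternative without the 3 noisiest arrays and the tests of explanations, which came later. The rule takes up to 12 loci per direction, private segments of 10 or more probes, and the 10 regions found in most animals. Other named probes were chosen after their values were seen.

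The limma step was tested on simulated data for ICSI-derived against naturally born animals. Of probes changed by 0.3, 0.6 and 1 on the log2 scale it recovered 19.4%, 74.6% and 100%, with 3 false calls among 161460 probes. Segmentation was tested on simulated data over the same number of probes. At a level of 0.6 it recovered 100% of segments of 5 probes with the noise of the quietest array and 6.67% with that of the noisiest, and for segments of 10 probes 100% and 90.0%. At a level of 0.4, nearer to most of the segments named in the report, it recovered 20.0% and 0.0% of segments of 5 probes, 96.7% and 6.67% of those of 10 probes, and 100% and 90.0% of those of 20 probes. Lower levels were not tested. No false segment was called. Both simulations drew noise independently for each probe, so they do not show how many false calls real arrays give.

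Gene-level results, gene lists, fixed genes and the probes of the transgene's promoter were planned and not run, because the files used here carry no gene names and the annotation used here is of another build. The correction for GC content was not run for the same reason. Normexp was run on median intensities, since the scanner files hold no mean spot intensities. Alternatives were other centring, normexp, loess, the value table, filters on dim and flagged probes, slide as a block and within slides, the replicate number as a block, no sex term, array weights, other segmentation settings and leaving out each animal. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and numba 0.67.0 were used for the other steps.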

Results

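Genomic DNA from liver was compared by array-based comparative genomic hybridisation in 10 mice of the ZFLacZ transgenic line. The 5 ICSI-derived animals were progeny obtained by intracytoplasmic sperm injection, in which a single sperm is injected into an oocyte, from testis cells kept frozen for 14 years. The 5 naturally born animals were progeny of the same line. Each group held 3 animals labelled male and 2 labelled female. Each animal's DNA carried the Cy5 dye and was hybridised with a Cy3-labelled pool of equal amounts of DNA from C57BL/6, SJL and DBA mice. A log2 ratio above 0 is therefore more signal from the animal's DNA than from the pool. According to the labels the oocytes behind the ICSI-derived animals came from DBA x C57BL/6 females, while the transgenic line goes back to SJL x C57BL/6, so strain background and the way the animals were made change together between the groups. Of 174305 non-control spots per array, between 173864 and 174090 were well above background in both channels, and the number of arrays limits the precision.

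Chromosomes X and Y separated the animals labelled female from those labelled male, except for one array. Chromosome X had a mean log2 ratio of 0.27 ± 0.01 (SD, n = 4) in the females, against values from -0.61 to -0.55 in 5 of the 6 labelled males. Chromosome Y had a mean of -1.50 ± 0.07 (SD, n = 4) in the females and lay between 0.75 and 0.82 in the same 5 males. The array labelled naturally born replicate 3, a male by its label, lay between the sexes on both, at -0.033 on chromosome X and -0.0072 on chromosome Y. Over all 10 animals the females exceeded the males on chromosome X by 0.76 and the males exceeded the females on chromosome Y by 2.15 (exact permutation test, two-sided, p = 0.00476 for each, the smallest p this design can give). Without that array the differences were 0.85 and 2.28. The size of the chromosome Y difference depended on the processing and on the probes used. It was 0.50 with normexp and 1.19 over probes well above background on all arrays, with the same p. That filter asks for signal on the arrays of the 4 females too and leaves out probes dim there, so a smaller difference is partly built into it.

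**Figure D1:**
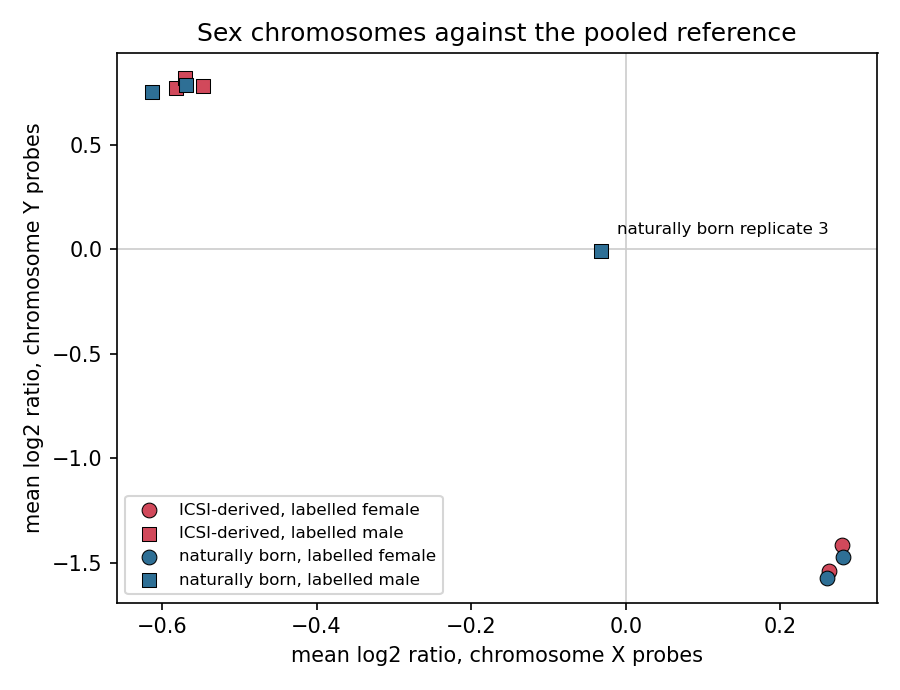
Mean log2 ratio of chromosome X probes (horizontal axis) against that of chromosome Y probes (vertical axis), 1 point per animal, coloured by group and with squares for labelled males and circles for labelled females. The array labelled naturally born replicate 3 lies at -0.033 and -0.0072, away from both clusters.

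The question of the main comparison was whether animals derived from long-frozen germ cells differ in DNA copy number from naturally born ones. Few probes differed between the groups: 25 autosomal probes were higher and 7 lower in ICSI-derived animals, of 161460 tested with limma. Of these 32 probes, 20 lay on chromosome 6 and 6 on chromosome 5, with the other 6 on 6 further chromosomes. The chromosome 5 probes, singled out after their values were seen, lay up to 16.5 Mb apart, and the neighbours of each averaged a difference between 0.01 and 0.05. Differences at such single probes do not show a change in the copy number of a stretch. The probe at 115807356 to 115807415 was lower in ICSI-derived animals by a log2 difference of -1.88 ± 0.07 (SE, limma adjusted p = 2.75e-07), with a mean difference of 0.01 over its neighbours. The probe at 131013744 to 131013803 was higher by 2.53 ± 0.21 (SE, limma adjusted p = 0.000475), and its neighbours averaged 0.05. The probe at 127718236 to 127718295 was lower by -1.19 ± 0.06 (SE, limma adjusted p = 6.29e-06), and its neighbours averaged 0.02. At an unadjusted p under 0.05, limma picked out 5274 autosomal probes, against 8073 expected by chance.

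Single animals moved these counts. Without ICSI-derived replicate 3 there were 47 probes higher and 30 lower, and the lower count fell to 4 without ICSI-derived replicate 1, without naturally born replicate 1 or without the array labelled naturally born replicate 3. The last of these left 22 probes higher. With slide as a block the counts were 24 and 5. Within slide 1 alone they were 20 and 17, and within slide 2 alone, which holds the array labelled naturally born replicate 3, 119 and 107. The fits within a slide rest on 4 arrays each and leave few degrees of freedom, so their counts are uncertain. Whether that array causes the rise was not tested.

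A single locus held 15 of the 25 higher probes, and no locus was made of lower probes. It spanned 394 kb of chromosome 6 (mm9, 41018389 to 41412425) and held 34 probes, 1 of which, at 41144824 to 41144883, was called lower. Over all 34, the mean log2 ratio was 0.26 ± 0.01 in ICSI-derived animals (SD, n = 5) and -0.07 ± 0.04 in naturally born animals (SD, n = 5). Every ICSI-derived animal lay above every naturally born one (exact permutation test, two-sided, p = 0.00794, the smallest this design can give). The locus was chosen by the probe test on the same animals. Segmentation found 2 stretches in it, which do not hold exactly the called probes: the called probe at 41112698 is in neither core and the second core holds 1 probe that was not called. In the first, 9 probes from 41018389 to 41101563 averaged 0.61 ± 0.02 in ICSI-derived animals and -0.27 ± 0.08 in naturally born animals (SD, n = 5 each). In the second, 6 probes from 41306470 to 41412425 averaged 0.51 ± 0.05 and -0.10 ± 0.07 (SD, n = 5 each). The locus count was 0 within slide 1 and 7 within slide 2. It rose to 2 without ICSI-derived replicate 2 and without ICSI-derived replicate 3, and in the latter case 2 loci of lower probes appeared.

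**Figure D2:**
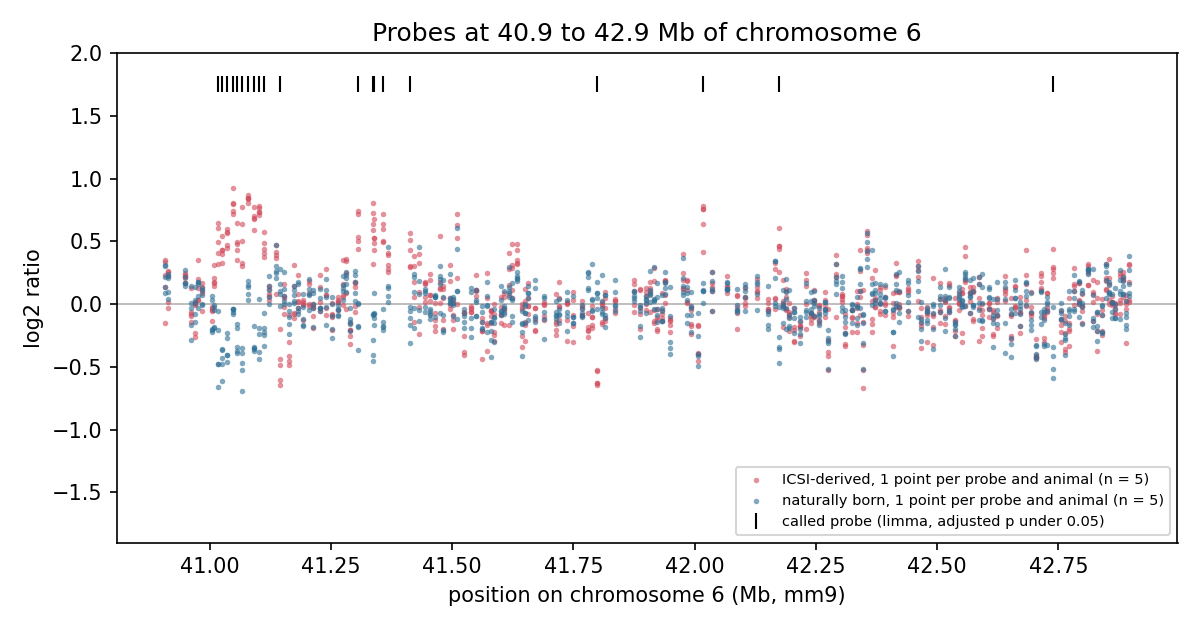
Log2 ratio (vertical axis) of 177 probes by position on chromosome 6 (horizontal axis, Mb, mm9), 1 point per probe and animal, coloured by group, with a tick above each of the 20 probes called by limma. In the stretch from 41018389 to 41101563 the ICSI-derived animals average 0.61 and the naturally born animals -0.27.

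The number of copy number segments, stretches of 5 or more probes at a constant level of at least 0.25 from 0, did not differ detectably between the groups. ICSI-derived animals carried 26.4 ± 11.5 segments and naturally born animals 28.0 ± 5.83 (SD, n = 5 each; exact permutation test, two-sided, p = 0.81). The segments of an animal covered 5.41 ± 0.88 Mb in the ICSI-derived group and 6.56 ± 1.32 Mb in the naturally born group (SD, n = 5 each; exact permutation test, two-sided, p = 0.135). Across all animals there were 272 segments, 119 gains and 153 losses, with a median length of 117 kb and a median of 8 probes. The 3 arrays with the most noise between neighbouring probes, ICSI-derived replicates 1 and 4 and naturally born replicate 2, had 17, 11 and 20 segments, and leaving all 3 out turned the difference in segment number to 4.67 more in ICSI-derived animals (exact permutation test, p = 0.2), a choice made after seeing the data. The difference also turned to 0.75 without ICSI-derived replicate 1, 2.25 without ICSI-derived replicate 4 and 0.4 without naturally born replicate 4, and was 2.5 within slide 1 and -8.5 within slide 2. For segment length it was -0.26 Mb and -2.55 Mb within these slides. Leaving out ICSI-derived replicate 2 brought the difference in length to -1.47 Mb (exact permutation test, p = 0.0476), and leaving out naturally born replicate 4 to -0.59 Mb (exact permutation test, p = 0.27). It was also smaller with other settings: -0.56 Mb with a minimum of 10 probes, -0.60 Mb at a threshold of 0.4, -0.61 Mb with normexp and -0.64 Mb with a penalty factor of 6.

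**Figure D3:**
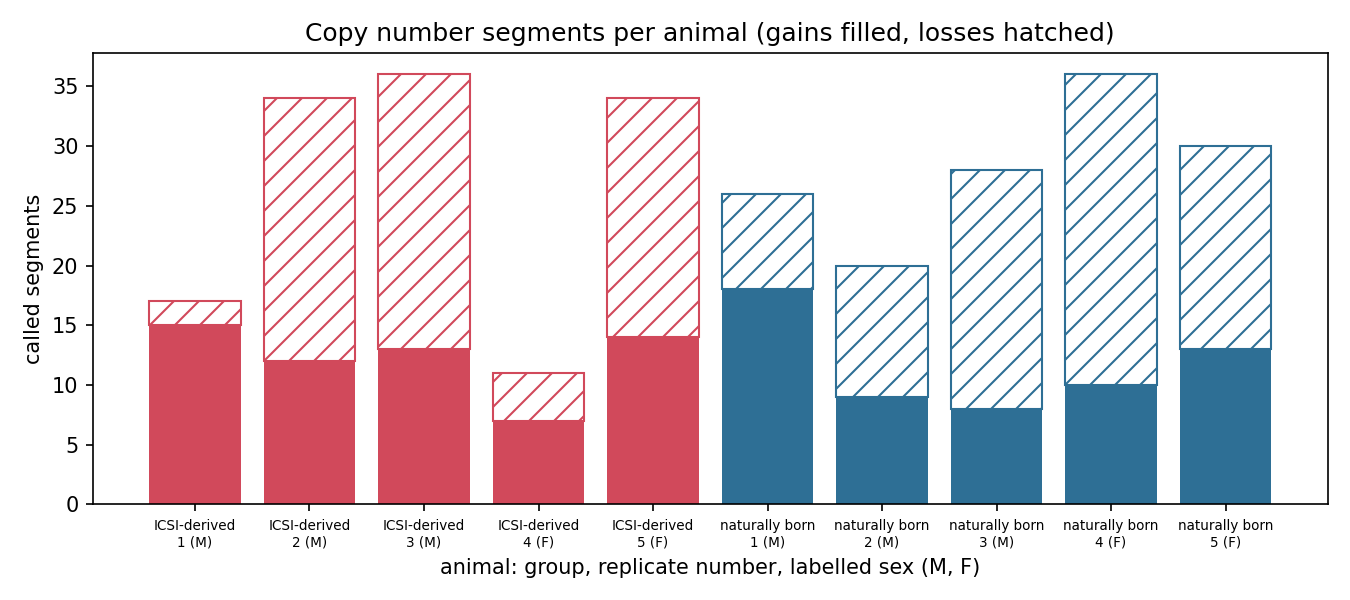
Number of called segments (vertical axis) in each of the 10 animals, filled bars for gains and hatched bars for losses against the pooled reference, coloured by group. Totals run from 11 to 36 in ICSI-derived animals and from 20 to 36 in naturally born animals.

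Most segments fell in regions shared between animals. Overlapping segments merged into 57 regions, of which 39 were found in 2 or more animals, 31 in both groups and 3 in all 10 animals. A region counts as found in an animal only where a segment was called, so animals at the same level can be missed. As examples picked by their values, a core on chromosome 10 (22006887 to 22072759) lay between -0.43 and -0.31 in all 10 animals, with calls in 2. A core on chromosome 16 (74549019 to 74703823) lay between -0.68 and -0.46, with a call in 1. The region found in all animals with the most probes lay on chromosome 4 (111718181 to 113993176, 141 probes). Its core of 40 probes, from 112627357 to 113251939, was at 1.14 in ICSI-derived replicate 1, between 0.38 and 0.45 in 3 animals of both groups, and between -1.70 and -1.43 in the other 6. A core on chromosome 4 at 121649423 to 121767386 sorted the animals in the same way, with 1.45 in ICSI-derived replicate 1 and values from -3.37 to -2.96 in the same 6 animals. A core on chromosome 11 (71032791 to 71107103) was gained in all 10 animals, at 2 levels: between 0.55 and 0.61 in ICSI-derived replicates 2, 3 and 4 and naturally born replicate 5, and between 1.35 and 1.45 in the other 6. The second chromosome 4 region of all animals (core 145018403 to 145192926) was lost throughout, from -0.83 to -0.35. Gains were also frequent on chromosome 1 (core 141582304 to 141678786, 9 animals) and chromosome 5 (core 105142362 to 105237345, 8 animals).

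Some losses found in 7 animals varied more among ICSI-derived than among naturally born animals. On chromosome 14 (core 69876584 to 70083135) the naturally born animals were at -0.37 ± 0.03 (SD, n = 5), while the ICSI-derived animals ranged from -0.42 to 0.21, with a mean of -0.05 ± 0.32 (SD, n = 5). On chromosome 3 (core 34295130 to 34515512) the corresponding means were -0.40 ± 0.02 and -0.19 ± 0.27 (SD, n = 5 each). On chromosome 7 (core 17223386 to 17278987) they were -0.50 ± 0.04 and -0.44 ± 0.17 (SD, n = 5 each). The loss on chromosome 17 (core 30586287 to 31019028, 47 probes) varied in both groups, at -0.20 ± 0.21 in naturally born and -0.16 ± 0.29 in ICSI-derived animals (SD, n = 5 each). Of the 57 regions, 3 parted the groups completely (exact permutation test, two-sided, p = 0.00794, Benjamini-Hochberg adjusted p = 0.151). They were the 2 stretches of the chromosome 6 locus and a core on chromosome 9 (39198693 to 39243125), at 0.35 ± 0.34 in ICSI-derived and -0.34 ± 0.03 in naturally born animals (SD, n = 5 each). There ICSI-derived replicate 3, at -0.25, lay close to the naturally born animals, at -0.38 to -0.31, and the other 4 ICSI-derived animals lay between 0.46 and 0.57.

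**Figure D4:**
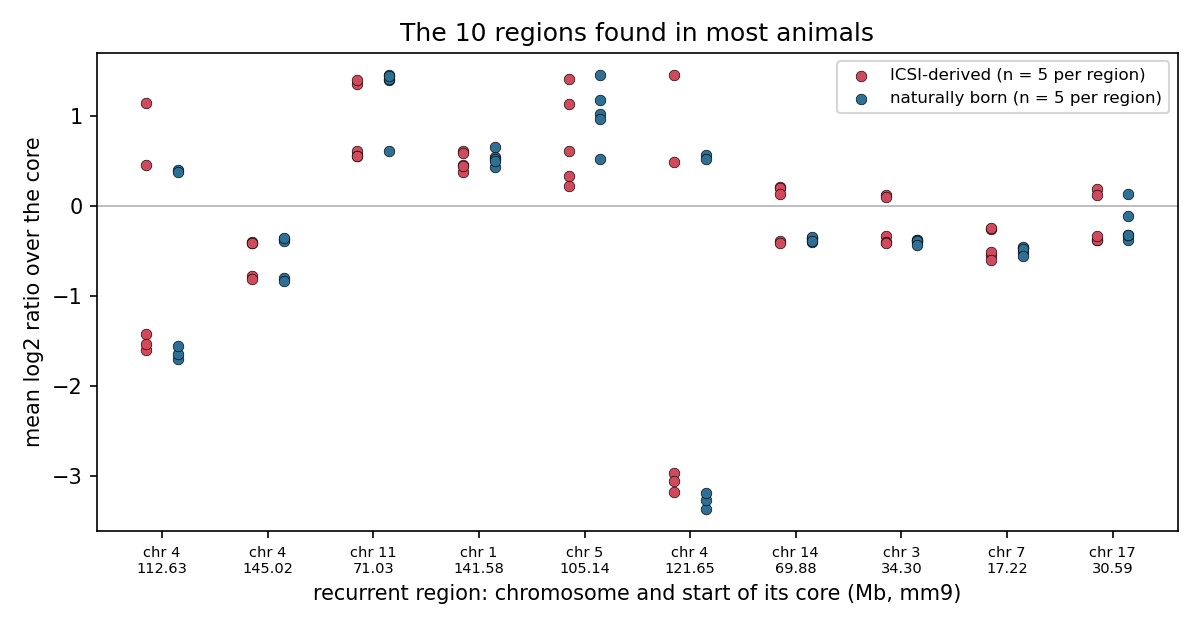
Mean log2 ratio over the core (vertical axis) of the 10 regions found in most animals (horizontal axis, chromosome and start of the core in Mb, mm9), 1 point per animal, coloured by group. At the chromosome 14 region the naturally born animals cluster around -0.37 while the ICSI-derived animals range from -0.42 to 0.21.

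Private segments, those that no segment of the same direction in another animal overlapped, numbered 1.4 ± 1.14 in ICSI-derived animals and 3.0 ± 1.0 in naturally born animals (SD, n = 5 each; exact permutation test, two-sided, p = 0.0873), a difference that did not pass the test. With the arrays centred on all probes the test passed its threshold (exact permutation test, p = 0.0476), with the lower mean again in ICSI-derived animals. With a penalty factor of 6 and with normexp the direction turned, to 0.6 more in ICSI-derived animals with each. Within slides 1 and 2 the difference was -1.0 and -2.5. It ran from -2.3 without ICSI-derived replicate 1 to -1.0 without ICSI-derived replicate 4. Private refers to the calls, and other animals can lie at the same level without one. Of the 22 private segments, 14 had a mean outside the range of the other 9 animals, and 1 lay more than 0.25 beyond the nearest of them. That one was a gain of 11 probes on chromosome 1 (90115633 to 90209508) in ICSI-derived replicate 1, at 0.57 against a range of -0.47 to 0.21 in the others, 3 of which had a loss called there. In all, 4 private segments lay in regions where other animals had segments of the opposite direction, the others being those on chromosomes 6, 9 and 12 (41018389, 39198693 and 114929341). The other private segments of 10 or more probes had neighbours in level among the other animals. In ICSI-derived animals they were gains on chromosome 1 (175929276 to 176063234, replicate 3, 0.36) and chromosome 3 (49159807 to 49397682, replicate 5, 0.34). In naturally born replicate 2 there was a loss on chromosome 12 (114929341 to 115163572, -0.29). The array labelled naturally born replicate 3 had gains on chromosome 12 (88794160 to 89611168, 0.27) and chromosome 18 (74489753 to 74648686, 0.31). Naturally born replicate 4 had a gain on chromosome 17 (34117148 to 34226193, 0.45) and a loss on chromosome 9 (39198693 to 39288078, -0.36), and naturally born replicate 5 had a gain on chromosome 15 (19260650 to 19736735, 0.33).

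Autosome means stayed far below the size of a whole-copy change in all 10 animals. The autosome mean farthest from 0 was that of chromosome 6 in naturally born replicate 5, at 0.069, while the other 9 animals lay between -0.0039 and 0.012 on that chromosome. The next was chromosome 11 of naturally born replicate 2, at 0.044. For scale, the change from 1 to 2 copies of chromosome X gave 0.85 between the males and females whose labels matched their chromosomes. Group means differed by at most 0.012, on chromosome 14, which also had the smallest unadjusted p (exact permutation test, two-sided, p = 0.0476, Benjamini-Hochberg adjusted p = 0.905).

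**Figure D5:**
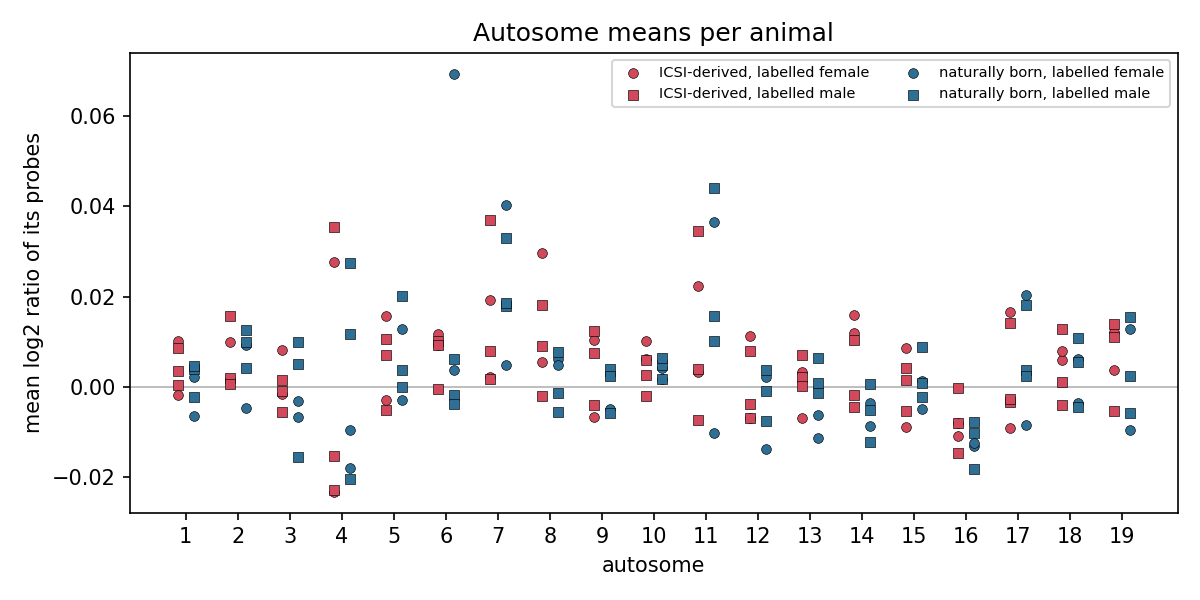
Mean log2 ratio of the probes of each autosome (vertical axis) by chromosome (horizontal axis), 1 point per animal, coloured by group and with squares for labelled males and circles for labelled females. Chromosome 6 of naturally born replicate 5 stands at 0.069, apart from the other 9 animals.

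The group difference did not depend detectably on sex. No autosomal probe passed limma's test of the interaction of group and sex, and 6130 had an unadjusted p under 0.05, against 8073 expected by chance. The count of probes that passed was 1 without ICSI-derived replicate 1, without naturally born replicate 4 or without naturally born replicate 5. With 2 labelled females per group, this test can miss a dependence on sex. On chromosome X, limma called 2 probes higher in ICSI-derived animals of 8723 tested, at 54806186 to 54806245 and at 166404052 to 166404111. The animals of each group were far apart on the first, from -4.19 to 0.89 in ICSI-derived and from -4.92 to 0.80 in naturally born animals. The second ranged from -0.94 to 1.14 and from -0.82 to 0.21. The limma fit on chromosome X gave all probes one shared spread, so these calls do not hold up against the spread between the animals on the probes themselves. Without the array labelled naturally born replicate 3 there was no call, and without naturally born replicate 5 there were 5.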

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

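Of 72 sets of 4 to 6 values, 5 had a value far from the others of its set, and chance alone gives about 1 in 20. The tests of a single animal's DNA, compressed ratios, mixed DNA, a trend, strong regions, slides, linked variants and the splits for autosomal probes and loci were chosen only after the result was seen. Those of the Cy3 signal and of the splits for chromosome X were set before their values were seen.

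On chromosomes X and Y the array labelled naturally born replicate 3 lay far from the other labelled males, at -0.033 against a range of -0.61 to -0.55 and at -0.0072 against 0.75 to 0.82. DNA of a single XY, XX or XXY animal would put chromosome Y at the level of one sex, and -0.0072 is far from both. Reference DNA in the sample channel, or compressed ratios, would pull all probes towards 0, but over 101 autosomal probes that deviated alike in the other 9 animals the slope on the other naturally born arrays was 0.97, within the range of 0.96 to 1.00 for those arrays. A mixture of male and female DNA is a candidate explanation: the female share came to 57.3% from chromosome X and 53.0% from chromosome Y, but both shares were known when this test was added, so it adds little to the pattern itself. A test on chromosome X alleles placed 66.7% of 3 probes between the levels of the other males, which passed its limit and was set aside, after the number of probes was seen, as resting on too few, and a mosaic animal remains open beside mixed DNA.

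Chromosome 6 of naturally born replicate 5 had a mean of 0.069, against -0.0039 to 0.0061 in the rest of its group. No other autosome of that array was farther from 0 than -0.018 (chromosome 4), which argues against a trend across the array. All 30 bins of 5 Mb, or 100%, had a mean above 0, from 0.037 to 0.094, so a few strong regions do not account for it. The Cy3 signal of the chromosome differed from the other 9 arrays by -0.0024 and the Cy5 signal by 0.067. This places the shift in the channel of the animal's sample and not in that of the reference, without showing how it arose there. A low-level gain of the whole chromosome may be present, which at 1 extra copy would need 9.84% of cells, a hypothesis with no test of a biological explanation, since the design has no group for it.

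For the probes that separated the groups in the main comparison, 100 splits of the 10 animals were compared, the real one included. Of these, 3 gave 32 or more called autosomal probes, with 101 as the highest of the others. This share is under 0.05, but 2 other splits gave more calls than the real one. Because the test was also chosen after the result was seen, it does not exclude chance for the probe count. Nor can chance be excluded for the locus count, since 5 of 100 splits gave 1 locus or more (highest other 6). The same holds for chromosome X, where 89 splits gave 2 calls or more (highest other 7947). The other splits were not held to the equal slides and sexes of the real one, which limits all these counts. The split with 101 calls exchanged ICSI-derived replicate 3 with naturally born replicate 5. A structure of the animals beyond their groups could give this, but was not tested. A split of all slide 1 arrays plus naturally born replicate 5 gave 50, against 24 higher and 5 lower probes with slide as a block. Each slide holds as many ICSI-derived as naturally born animals of each sex, so a shift between slides cannot make a group difference, and the 28 of 32 probes called again with slide as a block decide nothing further. The 16 called probes outside the span of the locus formed 21 pairs less than 20 Mb apart, against 10 at most in 10000 draws of autosomal probes. This grouping on chromosomes 5 and 6 had been seen before, and any regional cause would give it. In the first stretch of the locus the ICSI-derived animals were alike, at 0.61 ± 0.02 (SD, n = 5). The probe test that picked the locus favours probes at which the animals of a group are alike. This likeness therefore does not test whether changes arose separately in each animal. Inherited strain variants and an effect of freezing or injection common to all 5 animals cannot be told apart, because strain background changes together with the way the animals were made.

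Chromosome 6 of ICSI-derived replicate 2 was at -0.00046, below the range of 0.0093 to 0.012 of its group. The chromosome 11 core at 71032791 was at 0.61 in naturally born replicate 5, against 1.39 to 1.45 in its group.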

How the results depend on the processing

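The runs without the 3 noisiest arrays were chosen only after the result was seen. Of 232 alternative values for 12 results, 198 kept their direction and side of the threshold, or a count within 1.5 times. Some of them could hardly move. The autosome mean farthest from 0 stays the same when any animal but naturally born replicate 5 is left out. The value table differs from the processed intensities at 1 to 3 probes per array. Higher probes fell from 25 to 16 with normexp and to 16 without the 3 noisiest arrays, which also gave 1 lower locus. Within slide 1 there were 17 lower probes and 0 higher loci, and within slide 2 119 higher and 107 lower probes with 7 higher loci and 1 lower. These fits rest on 4 arrays each. Merging at 50 kb gave 2 higher loci. Leaving out single animals gave 22 to 47 higher and 4 to 30 lower probes, 1 to 2 higher and 0 to 2 lower loci, 0 to 1 interaction probes and 0 to 5 chromosome X probes. Differences below are ICSI-derived minus naturally born. The number of segments turned from -1.6 to 0.2 at a threshold of 0.4, 2.5 within slide 1 (-8.5 within slide 2) and 4.67 without the 3 noisiest arrays, and ran from -4.0 to 2.25 as single animals were left out. Segment length ran from -1.47 to -0.59 Mb as single animals were left out, and was -0.26 Mb within slide 1 and -2.55 Mb within slide 2. Private segments turned from -1.6 to 0.6 with a penalty factor of 6 and to 0.6 with normexp, and the difference of -1.8 with centring on all probes passed the test; leaving out single animals gave -2.3 to -1.0. For each of these the cause was not tested.

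Replicate numbers did not pair the animals: same-numbered animals' deviations correlated between -0.28 and 0.15, and none of the 5 ICSI-derived animals correlated best with its own number. With the replicate block there were 21 higher and 4 lower probes, and 25 of the 32 were called again. An exact permutation test within these pairs gave p = 0.875 for segment numbers, p = 0.312 for length and p = 0.0625, the smallest that 5 pairs can give, for private segments. Gene-level alternatives, the transgene promoter and the GC correction were not run. Signal over noise was high on all arrays, and noise between neighbouring probes limits short segments.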

Other observations

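All the tests here were chosen only after the result was seen. One of the 122 probes of chromosome Y was high in both sexes. At 607377 to 607436 the 4 females had a mean log2 ratio of 1.49 ± 0.22 (SD, n = 4) and the 5 males whose chromosomes matched their label 1.71 ± 0.25 (SD, n = 5), and the array labelled naturally born replicate 3 was at 1.35. The neighbouring probes, at 602022 and 618363, were at -2.06 ± 0.56 and -0.999 ± 0.12 in the females (SD, n = 4). A sequence carried by all 10 animals outside chromosome Y and scarce in the pool, such as part of the transgene, is a candidate source, as a hypothesis. The lowest female value was 1.25, while a probe that also binds sequence shared by both channels would lie near 0, but with no animal outside the line the transgene itself stays untested.

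A second stretch of chromosome Y read low in every animal. From 972031 to 1259990, 7 of 9 probes were below -0.3 in all 10 animals, with values from -3.19 to -0.52, in both sexes. The means of males and females were -2.77 and -2.86 at 1068101, and differed most at 1238158, at -1.50 and -1.09, and at 1259931, at -1.05 and -1.47. These probes enter the chromosome Y means of both sexes.

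Recurrent regions varied more among ICSI-derived animals. Over the 39 regions found in 2 or more animals, 30 had the larger SD in the ICSI-derived group, and the median log2 ratio of the SDs was 0.30 (exact permutation test over all splits into 5 and 5, two-sided, p = 0.0159). Without the array labelled naturally born replicate 3 the median was 0.17, with 29 regions wider in ICSI-derived animals, and without the 3 noisiest arrays it was 0.29, with 24. No test was run on either of these subsets. The regions were chosen from the same animals. This is consistent with a wider strain background of the ICSI-derived animals, whose mothers' strains the labels give as DBA and C57BL/6, a hypothesis that the median of 0.30 does not separate from other causes of variation.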
